A study of Mus musculus with 8 samples.

How the data were processed

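Single cells were profiled from the colonic lamina propria, the connective tissue layer beneath the gut epithelium, and from subcutaneous tumours. The mice lacked Gprc5a, a gene coding for an orphan G protein-coupled receptor best known as a tumour suppressor of the lung, and they had received faecal microbiota from a donor mouse. The donors lacked either Gprc5a alone (here the single-knockout donor) or both Gprc5a and Lcn2, which codes for the iron-chelating antimicrobial protein lipocalin 2 (the double-knockout donor). There were 8 libraries in 4 groups, 2 per tissue and donor. Per the labels, replicate 1 of each group came from a male and replicate 2 from a female mouse. The series gives 2 mice per group, and whether a lamina propria and a tumour library came from the same mouse is not given in the sources used here. Per the labels' protocols, each tissue was dissociated with a kit of its own, red cells were lysed, and cells negative for the dead-cell dye Sytox Green were sorted before loading on a 10x Chromium 5′ v2 kit.

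The deposited values were raw UMI counts per gene and barcode, whole numbers with no normalisation, made with Cell Ranger 7.1.0 per the matrix headers. The genome build was GRCm38 (mm10), and Seurat 3.1.5 was named, per the submitters' processing notes. The deposited barcodes had already been limited to those with at least 500 UMIs, as the lowest total per barcode in the count matrices showed. Each matrix held 32285 genes, of which 32158 matched the GENCODE mouse annotation of the same build by Ensembl identifier; coordinates come from that annotation. No table of cell types was used, so cell types were rebuilt here.

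Barcodes with under 200 genes or over 20% of UMIs from mitochondrially encoded genes were left out. Doublets were scored within each library as the share of simulated doublets, 2 per barcode, among a barcode's nearest neighbours. The highest scores were removed at 0.8% per 1000 barcodes, which came to between 3.04% and 17.1% of barcodes. Counts were scaled to 10000 UMIs per cell and log-transformed. Each tissue was then clustered on 30 principal components of 2000 variable genes with a graph of 20 neighbours, by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 2. Antigen receptor segments, ribosomal, mitochondrially encoded, predicted and sex-specific genes were kept out of the variable genes. There were 52 first clusters in lamina propria and 44 in tumour. After the data had been examined, 8 clusters with leading genes of more than 1 cell type were split on 15 components of 1000 genes at resolution 0.8, which gave 86 and 55 clusters. A type name below means a cluster that is like that type by its markers: at least 3 markers of the fixed list had to be detected in 10% of its cells, and clusters whose leading 10 genes went against the name stayed unnamed. In the lamina propria 1.66% ± 0.950 (SD, n = 2) of cells stayed unnamed in the single-knockout group and 1.12% ± 0.145 (SD, n = 2) in the double-knockout group. In tumours these shares were 1.52% ± 0.459 and 4.29% ± 2.53 (SD, n = 2 each). Lamina propria clusters for which no fixed list held are called by their genes: clusters 22a, 22c and 22h together are the Il23r and Cxcr6 cluster, and cluster 39 is the Kit and Etv1 cluster.

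Counts were summed per library and cell type, for types with at least 20 cells in each library. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test) between donor groups within a tissue. P-values were adjusted by the Benjamini-Hochberg method within each type at a threshold of 0.05. The replicate is the mouse, never the cell. Every log2 fold change is the double-knockout donor group over the single-knockout donor group, given with its standard error (SE), and levels are CPM, the summed counts scaled by library size, as mean ± SD of 2 libraries. An exact permutation test of 2 against 2 libraries has a smallest two-sided p of 0.333, so that test cannot reach 0.05 in this design. Cell shares were tested with the same edgeR model on cells per type, over all kept cells of a library. For 28 gene lists, camera of limma 3.58.1 tested whether the members shifted against the other genes of the type, with a preset correlation of 0.01. Lists needed at least 5 tested members, and adjustment ran over all list and type pairs of a tissue. The difference of the donor effect between tissues was tested as an interaction over all 8 libraries, in types with 20 cells in each. With 1 to 3 counts in a group a ratio of summed counts carries a 95% exact binomial interval, and with 0 counts a lower bound set at a floor of 3 counts over the group. Intervals and floors cover counting error only.

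The groups, tests, gene lists, cell type markers, naming rule and most alternative settings were fixed before the data were examined. By the naming rule, the types with most calls (at most 6 per tissue) gave their 2 largest increases and 2 largest decreases. These had an adjusted p under 0.05, both libraries of a group apart from both of the other, and at least 20 CPM in the higher group. The 4 list and type pairs of smallest camera p gave the 3 members of smallest edgeR p. Gprc5a, Lcn2, Xist, Ddx3y, S100a8, S100a9, Igha, Cd274, Ifng, Il17a, Il1b, Foxp3 and Cd8a were named in each tissue. Where the first part gave fewer than 10 genes, the 10 genes of smallest p were named as not having passed. Antigen receptor segments, haemoglobin, mitochondrially encoded, ribosomal, predicted, X-inactivation and Y-linked genes were left out of the first and last parts but stayed in all counts. Other called list members are given as examples chosen after their values were seen. A gene that this rule names is not reported here.

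Depth differed between libraries. In lamina propria the files held 76852973 UMIs in 9299 barcodes and 79010693 in 21315 for replicates 1 and 2 of the single-knockout group, and 44951734 in 7425 and 84807537 in 13505 for the double-knockout group. In tumours they held 23595768 in 4888 and 34730789 in 8835, then 31839847 in 3813 and 65865640 in 8175. Replicates of a group were not copies of a library: the chi-square of their counts over degrees of freedom was 318, 209, 82.9 and 146 in the 4 groups, for genes with at least 10 counts. Another scaling, the median ratio of DESeq2, moved the median of all genes by at most 0.016 on the log2 scale in any type.

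The steps were tested on data simulated from the real means and library sizes. Of genes planted at 4-fold edgeR recovered 77.9% in lamina propria fibroblasts (14789 genes tested), 97.9% in lamina propria macrophages (10634), 71.9% in tumour neutrophils (10772) and 81.9% in tumour macrophages (9880). At 2-fold these shares were 36.5%, 27.3%, 6.12% and 19.1%. Unchanged genes made up 16.8%, 13.5%, 10.7% and 10.4% of the calls, above the nominal 5%. Camera recovered all 4 planted lists in each simulation with its preset correlation, 0 with that estimated from 4 libraries, and fry 4, 2, 0 and 4. Draws from means carry no gene correlation, so the preset was not tested. For cell shares an 8-fold change was recovered in 44% of draws per tissue at a simulated dispersion of 0.3, with 1.53% of unchanged tests called in lamina propria and 4.91% in tumours. At a dispersion of 0.05 it was recovered in 99% and 98% of draws, with 12.1% and 14% of unchanged tests called.

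Other settings chosen in advance were DESeq2 1.42.0, its scaling within edgeR, no low-count filter, a filter against free RNA, summed counts of a type thinned to its smallest library, at least 50 cells, at least 1000 UMIs or at most 10% mitochondrial counts per cell, no doublet removal, naming by the best-scoring marker list, camera with an estimated correlation, fry, a replicate block, and leaving out each library in turn. Added after the data had been examined were fits without barcodes shared between libraries, without genes of the H2 region (chromosome 17, 33996017 to 37483552, 204 genes of the matrices) and Gm10260, and with crossed replicate numbers. The remaining tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.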

Results

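Live cells from colonic lamina propria and from subcutaneous tumours of Gprc5a-deficient mice were compared by the donor of their transferred faecal microbiota, which lacked Gprc5a alone or Gprc5a together with Lcn2. The comparison in each tissue was 2 against 2 libraries, and it asked how the donor's Lcn2 genotype, acting through the microbiota, went with gene expression and cell make-up. After filtering, 8524 and 17005 lamina propria cells were kept in the single-knockout donor group and 6177 and 11597 in the double-knockout donor group. In tumours 4694 and 8199 cells were kept against 3634 and 7530. Median depth of kept cells was 6812.5, 1264, 4420 and 4013 UMIs in lamina propria and 3324, 2141, 4556 and 4171 in tumour, in the same order, so replicate 2 of the lamina propria single-knockout group was the shallowest library. Within a tissue, replicates 1 and 2 are called SK1 and SK2 in the single-knockout donor group and DK1 and DK2 in the double-knockout donor group. All fold changes below are the double-knockout over the single-knockout donor group.

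Gprc5a transcripts were detected in every library although all recipients are labelled as knockouts, and 5′ counts cannot show whether the deleted part of the gene was present. In lamina propria epithelial cells Gprc5a stood at 51.7 CPM ± 6.96 (SD, n = 2) and 90.5 ± 11.4 (SD, n = 2), a log2 fold change of 0.95 (SE 0.20) that did not pass in edgeR (adjusted p = 0.695). Over all tumour cells it stood at 0.342 CPM ± 0.0940 (SD, n = 2) against 2.14 ± 0.313 (SD, n = 2), and in tumour carcinoma cells 0 and 4 UMIs were counted in 17 and 63 cells, against 46 and 120 in 300 and 611 cells, or 0 and 3.99 CPM against 8.62 and 11.1. Lcn2 was deleted in a donor strain only, so its level in recipients checks no label. It was measured at 38.2 and 14.1 against 6.16 and 7.52 CPM over all lamina propria cells, and at 301 CPM ± 54.2 (SD, n = 2) against 537 ± 33.7 (SD, n = 2) over all tumour cells. The sex-specific transcripts Xist (X inactivation) and Ddx3y (Y chromosome) went with the labelled sex in the 4 lamina propria libraries, though SK2, labelled female, had 7.24 CPM of Ddx3y, and 0.111 without the shared barcodes described below, against 0.0310 in DK2. In the tumour single-knockout group they went against it: SK1, the library labelled male, had 204 CPM of Xist and 0.0460 of Ddx3y, and SK2, the library labelled female, 21.9 and 62.4. In the tumour double-knockout group Ddx3y went with the label, at 55.8 CPM in DK1, labelled male, and 0.0340 in DK2, while Xist was high in both (243 and 372). Carcinoma cells carried Xist in all 4 tumour libraries (567, 634, 1301 and 1209 CPM), and in tumour macrophages it stood at 196, 0, 2.35 and 227 CPM in SK1, SK2, DK1 and DK2. Both libraries stand in the same donor group, so no donor contrast without a replicate block depends on which is which.

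Lamina propria SK2 shared an unusual number of cell barcodes with the other lamina propria libraries: 3567, 4671 and 3819, against 24 to 173 in the 21 library pairs that do not include it. Such barcodes made up 10365 of its 17005 kept cells (61.0%) and 27.1% of its kept UMIs, with a median of 839 UMIs against 3994 in the 6640 other cells. They were 85.3% of its plasma cells and 73.9% of its type 1 dendritic cells but 5.04% of its regulatory T cells. Lamina propria results were therefore also computed without them, with these changes of calls. Of 15 gene calls in edgeR 7 remained, 3 did not pass and 5, all immunoglobulin segments, were not tested. Another 13 were newly made, 6 in plasma cells, 4 in germinal centre B cells and 1 each in T cells, naive T cells and goblet cells. Of 88 camera calls of gene lists 75 remained, 9 were lost, 4 were not tested (MHC class II in T cells and lymphatic endothelium, C1q genes in plasma cells and stress genes in type 3 innate lymphoid cells) and 15 were newly made, the last with adjusted p = 0.882 to 0.980 with an estimated correlation.

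The 15 new list calls without shared barcodes were of MHC class II genes in type 2 dendritic cells (0.0235) and goblet cells (0.00918), cholesterol genes in germinal centre B cells (0.0485) and epithelial cells (0.0216), and matrix genes in blood endothelium (0.00614) and smooth muscle or pericytes (0.0420). Immunoglobulin genes in T cells (0.000683) and naive T cells (0.00943) and barrier genes in fibroblasts (0.00918) and plasma cells (0.0157) were others. The last were NF-κB targets in type 1 (0.0216) and acute inflammation and type 3 genes in type 2 dendritic cells (0.00635 and 0.0130), antimicrobial genes in macrophages (0.0496) and the regulatory T cell programme in regulatory T cells (0.0459), the only list of the 15 with a lower median (−0.33).

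Interferon-stimulated genes were lower in the colonic lamina propria of mice given microbiota from the double-knockout donor, most of all in epithelial cells. Targets of type I interferon, the antiviral cytokine family, were lower as a list in 9 of 17 tested cell types, and targets of interferon-γ, the macrophage-activating T cell cytokine, in 8 of 17. In epithelial cells all 27 tested type I targets had a lower estimate (median log2 −1.81, camera adjusted p = 9.5e-15). That call was lost at adjusted p = 0.919 with an estimated correlation. Single genes did not pass over all genes tested in edgeR, while 23 of the 27 passed when adjusted over the list alone. Oas3 and Oasl2, of the oligoadenylate synthetase family that senses viral RNA, had log2 fold changes of −1.90 (SE 0.37) and −1.84 (SE 0.38), and Zbp1, a sensor of Z-form nucleic acid, −1.40 (SE 0.29), each with adjusted p = 0.695. Their levels were 69.4 CPM ± 13.2, 215 ± 46.0 and 67.1 ± 11.7 (SD, n = 2) against 16.6 ± 8.39, 53.8 ± 28.1 and 22.8 ± 8.63 (SD, n = 2), and the donor groups did not overlap. Without DK1 they passed (adjusted p = 0.00936, 0.0121 and 0.0416), in a fit where the lone library is assumed to vary like the other pair, as in all fits leaving out a library. The make-up of the type differed too, with cluster 5 (Ly6g, Saa1, Ifit1bl1) at 8.82% of epithelial cells in the single-knockout group and 36.1% in the other, and cluster 8 at 23.2% and 16.3%.

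Goblet cells, fibroblasts, lymphatic endothelium and the Kit and Etv1 cluster showed the same direction for type I targets, with calls that each had an adjusted p = 0.919 with an estimated correlation. In goblet cells 20 of 23 were lower (median −1.13, adjusted p = 4.2e-10), with 10 lower and 2 higher when adjusted over the list alone. In fibroblasts 23 of 25 were lower (−0.57, 4.2e-10, 6 over the list alone), in lymphatic endothelium 16 of 16 (−0.94, 4.2e-09, 7) and in the Kit and Etv1 cluster 8 of 8 (−1.44, 4.2e-09, 6). Macrophages (−0.45), smooth muscle or pericytes (−0.48), B cells (−0.79) and blood endothelium (−0.26) were also called, again each at adjusted p = 0.919 with an estimated correlation. The call in blood endothelium was lost without DK2 (0.443). In goblet cells Ifi44 (log2 −3.26, SE 0.68) and Bst2, which tethers budding virus (−1.35, SE 0.30), stood against Oasl1 (1.18, SE 0.27), a negative regulator of interferon production, and none of them passed (edgeR adjusted p = 0.488 each). Without DK1 Ifi44 passed (0.0237), and without DK2 Oasl1 (0.0499).

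Among interferon-γ targets, 19 of 20 were lower in fibroblasts (median −0.71, adjusted p = 4.4e-14), 12 of them when adjusted over the list alone. That call and the other 7 below had an adjusted p = 0.919 with an estimated correlation. All 17 were lower in lymphatic endothelium (−1.08, 1.1e-09, 8 over the list alone), 11 of 12 in goblet cells (−0.91, 2.6e-07, 5) and 14 of 16 in epithelial cells (−1.33, 1.1e-06, 8). All 12 were lower in smooth muscle or pericytes (−0.55, 3.2e-07, 0 over the list alone). B cells (−0.32), blood endothelium (−0.22) and CD8 T cells (−0.26) were also called. These were lost in B cells without SK1 or DK1 (0.0760 and 0.0948), in blood endothelium without SK1 or DK2 (0.277 and 0.447) and in CD8 T cells without SK1, SK2 or DK2 (0.0628, 0.117 and 0.315). The chemokine Cxcl9, which draws activated T cells, stood at 27.2 CPM ± 0.398 (SD, n = 2) against 4.58 ± 0.662 (SD, n = 2) in fibroblasts (log2 −2.49, SE 0.17, edgeR adjusted p = 0.188). There the guanylate-binding protein gene Gbp3 (−1.05, SE 0.18) did not pass either (adjusted p = 0.601). Cxcl9 passed without SK1 or SK2 (0.0306 and 0.00550), and Gbp3 without SK2 (0.0261).

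Genes of MHC class I presentation, which display peptides to CD8 T cells, were lower as a list in 6 of 19 types, each at adjusted p = 0.919 with an estimated correlation. In fibroblasts all 18 were lower (median −0.56, adjusted p = 2.1e-12, 13 over the list alone), among them H2-Q6 (log2 −1.79, SE 0.26), H2-Q7 (−1.40, SE 0.24) and H2-T23 (−1.31, SE 0.23), none passing over all genes (edgeR adjusted p = 0.601 each, and 0.0131, 0.0450 and 0.0434 without SK2). In lymphatic endothelium 17 of 18 were lower (−0.55, 4.2e-10, 7 over the list alone). H2-Q genes are near-identical copies whose reads may be split between members, so their single values are uncertain. Without the H2 genes, the fibroblast and lymphatic calls stood at adjusted p = 6.7e-05 and 0.00166. The smaller shifts in smooth muscle or pericytes, B cells, epithelial and goblet cells (medians −0.19, −0.29, −0.30 and −0.16) were lost there, at 0.0757, 0.227, 0.0695 and 0.174. They were also lost in smooth muscle or pericytes without SK1 or DK1 (0.0531 and 0.143), in B cells without SK2 or DK2 (0.0706 and 0.110), in epithelial cells without SK2 (0.123) and in goblet cells without SK2, DK1 or DK2 (0.334, 0.224 and 0.0668).

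**Figure D1:**
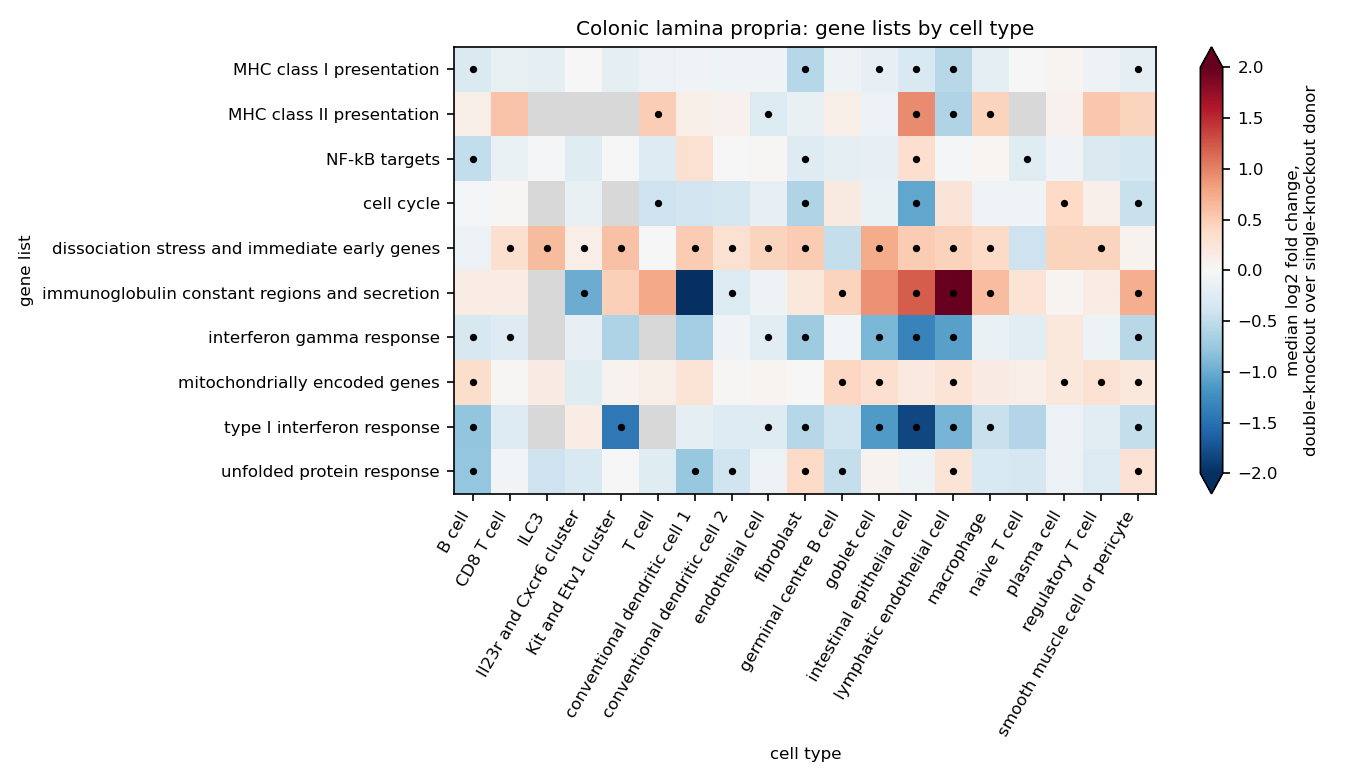
Heat map of the median log2 fold change of each gene list (vertical axis) in each lamina propria cell type (horizontal axis), double-knockout over single-knockout donor group, on a colour scale from −2 to 2; a black dot marks a camera call, grey means not tested, and the lists called in at least 4 types are drawn. Type I interferon targets reach −1.81 in epithelial cells, and stress genes are called higher in 13 of 19 types.

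Stress and immediate early genes, which respond within minutes to handling of tissue, moved the other way. They were higher as a list in 13 of 19 lamina propria types, for example 19 of 20 in goblet cells (median 0.75, camera adjusted p = 6.9e-09, 0 over the list alone) and 18 of 20 in lymphatic endothelium (0.46, 8.9e-08, 9 higher and 1 lower over the list alone). Each had an adjusted p = 0.919 with an estimated correlation. The calls in goblet cells, both endothelia and the Il23r and Cxcr6 cluster held in all 4 fits leaving out a library, and the other 9 did not. Calls were lost without DK1 in 7 types (0.116 to 0.875), without SK1 in 3 (0.235 to 0.386) and without SK2 in 4 (0.0522 to 0.211). Mitochondrially encoded genes were higher in 7 of 19 types, by medians of 0.21 to 0.42 (adjusted p = 0.919 to 0.923 with an estimated correlation), and each of these calls was lost without SK1 (0.151 to 0.562), 4 without DK1 (0.102 to 0.855) and 2 without DK2 (0.147 and 0.200).

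Only 15 gene calls were made in the lamina propria, 4 higher and 11 lower over 19 cell types and 154704 tests, with 8269 tests at an unadjusted p under 0.05. In all 15 the donor groups did not overlap, as calling favours. Type 1 conventional dendritic cells, which cross-present antigen to CD8 T cells, held 10 of them. There Ccl5 (ENSMUSG00000035042, GRCm38 chromosome 11, 83525778 to 83530518), a chemokine for T cells and monocytes, rose from 9.59 CPM ± 10.7 to 379 ± 355 (SD, n = 2 each, log2 5.98, SE 0.75, edgeR adjusted p = 0.000237). The immediate early transcription factor Egr1 rose by 1.69 (SE 0.27; 0.00451), from 125 CPM ± 33.7 to 375 ± 68.6 (SD, n = 2 each). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) fell from 138 CPM ± 90.4 to 17.3 ± 17.5 (SD, n = 2 each, log2 −3.67, SE 0.61; 0.00778). Igha, the IgA heavy chain made by plasma cells, was lower at 65.4 CPM ± 1.94 against 827 ± 939 (SD, n = 2 each, log2 −3.68, SE 0.67; 0.0157), and the joining chain of IgA, Jchain, was lower by a log2 of −3.54. Igha stood at 1491 CPM in SK1, 163 in SK2, 66.7 in DK1 and 64.0 in DK2. Without shared barcodes neither passed (adjusted p = 0.115 and 0.169), and without doublet removal the Igha estimate was 1.96, in the other direction. The remaining calls in this type were S100a10 (1.62) and 4 immunoglobulin variable segments, whose reads can be split between copies and which were not tested without shared barcodes.

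The type 1 dendritic cell calls rested on 126 and 180 against 31 and 68 cells. Leaving out SK1 ended all of them (adjusted p = 0.876 for each named gene), and without SK2 Ccl5, Egr1 and Cxcl9 stood at 0.999, 0.573 and 0.491, while Igha passed (0.0350) and the type held 0 genes higher and 9 lower in edgeR. The clusters holding most of the type also differed, cluster 41a with 38.2% and cluster 49 with 36.6% in the single-knockout group, and cluster 49 with 56.6% in the other. In DESeq2 198 genes were higher and 101 lower over all lamina propria types, and without shared barcodes 14 and 6 in edgeR. The edgeR counts were 542 and 429 without SK1, 1008 and 704 without SK2, 257 and 267 without DK1, and 367 and 168 without DK2.

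Ornithine decarboxylase, the enzyme that starts polyamine synthesis, fell in a pair of lymphocyte populations. Odc1 (ENSMUSG00000011179, chromosome 12, 17544794 to 17551505) dropped from 780 CPM ± 139 to 66.6 ± 44.9 (SD, n = 2 each) in regulatory T cells (log2 −3.19, SE 0.33, edgeR adjusted p = 0.00886). In the Il23r and Cxcr6 cluster, which carries receptors of type 3 lymphocytes and had 38.5% against 50.7% of its cells in cluster 22c, it dropped from 337 CPM ± 132 to 26.0 ± 19.3 (SD, n = 2 each, log2 −3.32, SE 0.43; 0.0115). Both calls held in all 4 fits leaving out a library, and without shared barcodes (0.0107 and 0.0255). Igkv8-30 and Gm30211 (log2 −3.21) were called lower in type 2 dendritic cells, of which shared barcodes made up 83.0% in SK2. Without shared barcodes that type held 0 calls in edgeR: Gm30211 stood at 1.000 and Igkv8-30 was not tested. The neuropeptide galanin, Gal, was higher in T cells at 151 CPM ± 31.0 against 3.55 ± 5.02 (SD, n = 2 each, edgeR adjusted p = 0.0392). It rested on 83 against 2 UMIs, a ratio of 29.2 with a 95% counting interval of 7.83 to 245, DESeq2 gave an adjusted p = 0.876, and Gal was not tested without DK2. T cells had 35.5% against 55.1% in cluster 24b and 50.7% against 41.1% in cluster 24c. No other lamina propria type held a call.

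Further lists shifted in single lamina propria types, all with adjusted p = 0.919 to 0.923 with an estimated correlation. Unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, were lower in B cells (median −0.77, 12 over the list alone), type 1 dendritic cells (−0.76, 8), type 2 dendritic cells (−0.40, 0) and germinal centre B cells (−0.47, 0). They were higher in fibroblasts, 16 of 16 (0.39, 5), in lymphatic endothelium (0.28, 0) and in smooth muscle or pericytes (0.29, 2). Without shared barcodes the type 2 dendritic cell call was lost (0.419). MHC class II genes were higher in macrophages (0.45, 3 over the list alone), epithelial cells (0.94, 0) and T cells (0.50, 1), and lower in lymphatic (−0.60, 1) and blood endothelium (−0.28, 1), the last lost without shared barcodes (0.587). Barrier and mucus genes were higher in goblet cells (0.46, 6 higher and 1 lower over the list alone), epithelial cells (0.39, 0) and macrophages (0.81, 0), and epithelial antimicrobial genes in goblet cells (0.94, 3). Most goblet cells lay in cluster 28 (Spink4, Reg4, Retnlb) in the single-knockout group, 73.6%, and in cluster 35 (Zg16, Tff3, Fcgbp) in the other, 62.7%. Other types differed in their clusters as well. Fibroblasts had 9.02% against 26.2% in cluster 1, 15.7% against 4.94% in cluster 3 and 11.6% against 2.03% in cluster 7, and macrophages 33.5% against 9.38% in cluster 23 (Mmp13, C1q) and 1.49% against 10.4% in cluster 34a, with leading genes (Ccr2, Il1b, Sirpb1c, Cd14) shared with monocyte cluster 34b. Cluster 26 held 82.3% and 37.7% of germinal centre B cells, cluster 14 held 43.6% and 7.15% of plasma cells and cluster 24a 31.4% and 60.2% of naive T cells. Germinal centre B cells numbered 29 and 458 in SK1 and SK2 and 55 and 744 in DK1 and DK2. The calls in B cells and fibroblasts (unfolded protein response), macrophages (MHC class II) and goblet cells (barrier genes) held in all 4 fits leaving out a library. The others were lost without SK1 in 7 pairs (0.141 to 0.883), SK2 in 4 (0.0513 to 0.297), DK1 in 5 (0.0568 to 0.425) or DK2 in 7 (0.0633 to 0.289).

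Cell cycle genes had a lower median in epithelial cells (−1.04), fibroblasts (−0.61), T cells (−0.42) and smooth muscle or pericytes (−0.45), and a higher median in plasma cells (0.40). These camera calls had adjusted p = 0.919 to 0.923 with an estimated correlation, 0 members passed over the list alone in edgeR, and each was lost without 1 library: SK1 for epithelial cells and fibroblasts, DK1 for T cells and smooth muscle or pericytes and DK2 for plasma cells. The other list calls also had adjusted p = 0.919 to 0.923 with an estimated correlation. NF-κB targets were lower in B cells (−0.49, 4 over the list alone), fibroblasts (−0.25, 0) and naive T cells (−0.25, 1), and higher in epithelial cells (0.34, 0). Immunoglobulin constant genes were higher in 5 types, up to a median of 3.04 in lymphatic endothelium, and lower in the Il23r and Cxcr6 cluster and type 2 dendritic cells. The lower calls were lost without shared barcodes (adjusted p = 0.205 and 0.897). Matrix genes were lower in epithelial, goblet and lymphatic cells and angiogenesis genes in type 2 dendritic and epithelial cells. Those 5 calls were also lost without shared barcodes (0.353, 0.454, 0.853, 0.165 and 0.232). Acute inflammation genes were higher in type 1 dendritic cells (1.01, 4) and lower in blood endothelium (−0.23, 1). Genes of C1q and resident macrophages were higher in epithelial cells (0.66) and lower in fibroblasts (−0.45) and plasma cells (−1.27), cholesterol genes higher in CD8 T cells (0.22), and hypoxia genes lower in regulatory T cells (−0.26) and type 1 dendritic cells (−0.28). From NF-κB targets on, the calls in B cells (NF-κB), the Il23r and Cxcr6 cluster (immunoglobulin) and lymphatic endothelium (matrix) held in all 4 fits leaving out a library. The others were lost without SK1 in 11 pairs, SK2 in 6, DK1 in 11 or DK2 in 10. Free RNA may underlie the immunoglobulin calls outside B cells, the C1q calls and the barrier call in macrophages. Aryl hydrocarbon receptor targets, checkpoint ligands, cytotoxic genes, haemoglobin, inhibitory receptors, the regulatory T cell programme, sex-specific genes, suppressive macrophage genes and type 2 and type 3 immunity had no lamina propria call. Over all lists 88 of 351 pairs were called, 40 higher and 48 lower, of which 26 held in all 4 fits leaving out a library. Camera with an estimated correlation and fry called 0, with 4 and 25 pairs at an unadjusted p under 0.05, and leaving out SK2 gave 149.

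Other genes named in advance did not pass in the lamina propria. Estimates were −0.73 (SE 0.31) for Foxp3, the master factor of regulatory T cells, in those cells, and −1.24 (SE 0.78) for Il17a in the Il23r and Cxcr6 cluster. Ifng (0.78, SE 0.43) and Cd8a (−0.66, SE 0.35) were measured in CD8 T cells, Il1b (0.55, SE 0.27) in macrophages and Cd274, which codes for PD-L1, in B cells (0.25, SE 0.23). Igha in plasma cells (0.04, SE 0.82), Lcn2 in lymphatic endothelium (−0.90, SE 0.24) and S100a9 in innate lymphoid cells (0.88, SE 0.87) did not pass either. The lowest adjusted p among these was 0.766 in edgeR, and S100a8 was only measured over all cells, at 3.71 CPM ± 2.44 against 1.14 ± 0.434 (SD, n = 2 each). Genes of smallest p that missed the threshold included Ccl21a, a chemokine of lymphatic vessels, in blood endothelium (log2 −3.04, SE 0.34, edgeR adjusted p = 0.120) and Gsdmc4, a gasdermin, in goblet cells (2.75, SE 0.28; 0.146). Kcnb2 (2.43, SE 0.29) and Kcnip4 (1.66, SE 0.21), a potassium channel and a channel-interacting protein, stood at 0.117 in the Kit and Etv1 cluster. Serpina3n in lymphatic endothelium (−2.06, SE 0.30; 0.152), Il22ra2, the decoy receptor of interleukin 22, in type 2 dendritic cells (2.01, SE 0.24; 0.0951), Igkc (1.85, SE 0.18; 0.103) and Efcab11 (1.87, SE 0.20; 0.126) in macrophages and the histone gene Hist1h2ap in plasma cells (1.98, SE 0.15; 0.0854) completed this set. Igkc and Hist1h2ap have near-identical relatives and are uncertain. Without shared barcodes the SK2 level went from 48.2 to 6.81 CPM for Ccl21a (then not tested), from 34.7 to 0 for Il22ra2 (adjusted p = 1.000), from 258 to 47.6 for Igkc (0.797), from 51.3 to 20.3 for Kcnb2 (0.261), from 11.4 to 6.39 for Efcab11 (0.174), from 6.60 to 3.82 for Gsdmc4 (0.0991) and from 5.35 to 8.33 for Hist1h2ap (0.472). That of Il17a went from 62.5 to 30.5 (0.999) and of S100a9 from 72.0 to 0 (not tested). Of the named lamina propria genes, 8, 15, 11 and 8 newly passed without SK1, SK2, DK1 and DK2, among them Kcnb2, Kcnip4 and Igkc in each of these fits and Lcn2 without SK2 (0.00121). Il17a had an estimate of 1.74 without SK1 (adjusted p = 0.0114) and of −2.05 and −3.31 without SK2 and DK2 (1.87e-10 and 3.94e-06). Cd8a passed at −1.11 without SK1 (0.000801) and Foxp3 at −1.42 without DK2 (0.0379).

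Cell shares of the lamina propria did not pass for any of 27 types in edgeR, with 1 at an unadjusted p under 0.05. That type was the B cell, 1.37% ± 0.522 of kept cells against 5.46% ± 2.93 (SD, n = 2 each, log2 2.00, SE 0.74, adjusted p = 0.819, exact p = 0.333), and leaving out any library gave 0 calls. Fibroblasts made up 44.1% ± 11.4 against 33.1% ± 0.426, epithelial cells 10.1% ± 10.6 against 18.8% ± 8.84 and plasma cells 7.30% ± 3.46 against 6.71% ± 0.143 (SD, n = 2 each). Without shared barcodes the plasma cell share of the single-knockout group was 4.26% ± 0.847 (SD, n = 2), as SK2 went from 9.75% to 3.66%, and the estimate went from −0.12 to 0.66, while that of B cells went from 2.00 to 1.27, neither passing. These shares depend on the live-cell sort and on the 40.9% of kept cells of SK2 that had under 1000 UMIs.

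CD8 T cells of the tumours carried more proliferation and sterol synthesis transcripts and fewer effector transcripts after transfer from the double-knockout donor. All 28 cell cycle genes had a higher estimate (median 1.51, camera adjusted p = 9.8e-19), and 16 passed over all genes and 28 when adjusted over the list alone. With an estimated correlation the list stood at adjusted p = 0.746. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), the standard mark of cycling cells, rose from 100.5 CPM ± 2.47 to 325 ± 35.6 (SD, n = 2 each, log2 1.73, SE 0.16, edgeR adjusted p = 0.0257). Top2a, the topoisomerase that untangles chromosomes, rose by 1.64 (SE 0.16; 0.0257) and the centromere protein gene Cenpf by 2.15 (SE 0.18; 0.0253). Cholesterol synthesis genes were higher for 17 of 17 (median 1.43, 5.1e-11), with 5 passing over all genes and 17 over the list alone, and the list stood at adjusted p = 0.746 with an estimated correlation. Among them were Hmgcs1 (log2 1.66, SE 0.21, adjusted p = 0.0326) and Fdps (2.04, SE 0.32; 0.0448), enzymes of the mevalonate pathway, and Insig1 (2.13, SE 0.27; 0.0328), which holds back sterol sensing.

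Cytotoxic genes of tumour CD8 T cells were lower for 13 of 19 (median −0.52, camera adjusted p = 0.00123), with 4 passing over all genes and 10 lower and 1 higher over the list alone, and stood at adjusted p = 0.746 with an estimated correlation. Ccl5 fell from 6497 CPM ± 24.1 to 899 ± 214 (SD, n = 2 each, log2 −2.81, SE 0.20, edgeR adjusted p = 0.0218), the effector transcription factor Eomes by 2.16 on the log2 scale and perforin, Prf1, by 1.09. Granzyme E, Gzme (ENSMUSG00000022156, chromosome 14, 56117626 to 56120625), fell from 139 CPM ± 49.2 to 17.4 ± 5.13 (SD, n = 2 each, log2 −2.99, SE 0.35; 0.0304), and the carboxypeptidase gene Cpq from 20.2 ± 0.241 to 2.30 ± 1.56 (−3.29, SE 0.47; 0.0380). Targets of interferon-γ (17 of 18 lower, median −0.69, 10 over the list alone) and of type I interferon (22 of 23, −0.98, 9) were called lower at adjusted p = 1.0e-05 and 6.4e-07. With an estimated correlation they stood at adjusted p = 0.746 and 0.755. Checkpoint ligands were lower for 8 of 9 (−0.44, adjusted p = 0.777 with an estimated correlation), with Cd86 (−1.94) and Vsir (−1.20) passing, though not without SK1 (0.0507 and 0.102), and the list was lost without DK2 (0.136). MHC class I genes were lower (−0.40, adjusted p = 0.755 with an estimated correlation), but not without the H2 region (0.414). Ifng stood at 623 CPM ± 154 against 635 ± 341 (SD, n = 2 each, log2 0.06, SE 0.38) and Cd8a had an estimate of −0.03 (SE 0.16), neither passing (edgeR adjusted p = 0.942 each). Matrix genes, of untested source, were higher in these libraries too (median 2.02 over 9 genes, adjusted p = 0.755 with an estimated correlation, lost without DK1), and the epithelial keratin Krt18 stood at 2.31 CPM ± 1.83 against 10.9 ± 6.53 (SD, n = 2 each).

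Tumour CD8 T cells held 137 genes called higher and 47 lower, the most of any type. No CD8 call remained without DK1 or DK2: the named genes stood at adjusted p = 0.148 without DK1 and 0.318 to 0.391 without DK2. Without SK1, the library labelled male, 59 and 29 were called, with Top2a, Hmgcs1, Insig1 and Fdps at 0.0507, 0.0615, 0.0507 and 0.0701. Without SK2, 226 and 178 were called. Clusters 26a and 26d, of cycling genes, and 26c, which also had Trgv2, Tcrg-C2 and Klra5 among its leading genes, held 0.425%, 0.340% and 0.425% of CD8 T cells in the single-knockout group and 12.6%, 5.44% and 7.82% in the other, while clusters 26b and 26f held 3.57% and 0.170% against 3.58% and 1.06%. The Gzmk and Cxcr3 cluster 16 held 37.9% and 17.5%.

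**Figure D2:**
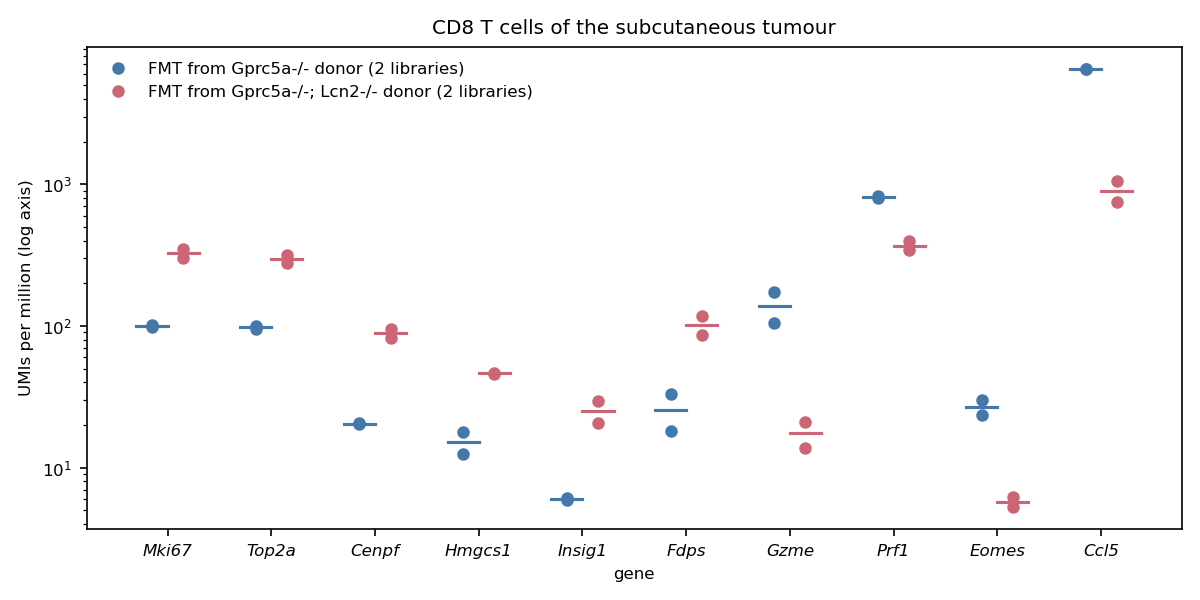
CPM of summed counts in tumour CD8 T cells (vertical axis, log scale) for 10 genes chosen among the calls (horizontal axis), with a point per library and a bar at the mean of each donor group of 2 libraries. Mki67 sits at a mean of 100.5 against 325 CPM and Ccl5 at 6497 against 899 CPM. The donor groups do not overlap for any gene drawn, as in all 442 tumour calls.

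Tumour macrophages had more transcripts of resident and C1q-expressing macrophages after transfer from the double-knockout donor. Genes of C1q and resident macrophages were higher for 9 of 10 (median 1.42, camera adjusted p = 1.0e-05, adjusted p = 0.746 with an estimated correlation), with 3 passing over all genes and 8 over the list alone. Selenop, a selenium carrier, rose from 21.9 CPM ± 1.01 to 149 ± 28.5 (SD, n = 2 each, log2 2.67, SE 0.24, edgeR adjusted p = 0.00480), and Adgre1, which codes for F4/80, by 1.67. The mannose receptor Mrc1 rose by 1.24 and the lipid carrier Apoe by 2.26. The chemokine Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799) was at 125 CPM ± 76.8 against 0.679 ± 0.702 (SD, n = 2 each, 0.00528), on 1185 against 2 UMIs, a ratio of 493 with a 95% counting interval of 136 to 4073. Acute inflammation genes were lower for 15 of 22 (median −0.44, adjusted p = 0.755 with an estimated correlation), 7 lower and 1 higher over the list alone, and were not called without SK1 (0.543). The neutrophil chemokines Cxcl3 (log2 −2.68, adjusted p = 0.00480) and Cxcl1 (−1.91, 0.0394) and interleukin 6, Il6 (−1.34, 0.0366), fell. Arginase 1, Arg1 (−1.78), and osteopontin, Spp1 (−1.62), fell as well, while the list of suppressive macrophage genes was not called. The dendritic cell homing receptor Ccr7 fell by 3.23 (SE 0.38; 0.0141), but without SK2 it stood at 0.0777. Without SK1, Mrc1, Cxcl1, Il6 and Arg1 did not pass (0.0884, 0.0701, 0.0867 and 0.0949), and Mrc1 passed without DK1 only. The adhesion gene Nectin3 was at 0.293 CPM ± 0.415 against 36.1 ± 32.7 (SD, n = 2 each, 0.0177), on 1 against 336 UMIs, a ratio of 404 with an interval of 72.0 to 16007, and it was not tested without SK2.

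In the same macrophages, cell cycle genes were higher for 24 of 27 (median 1.09, camera adjusted p = 4.5e-10, adjusted p = 0.755 with an estimated correlation, 11 over the list alone), though Mki67 (log2 1.36, SE 0.31), Ube2c (2.77, SE 0.59) and Ccnb1 did not pass (edgeR adjusted p = 0.102, 0.0827 and 0.0911). Without DK2 Mki67 and Ube2c passed (0.0369 and 0.0329), and Ube2c also without SK2 or DK1 (0.0229 and 0.0356). Ccnb1 rested on 33 against 1 UMIs, a ratio of 27.4 with an interval of 4.59 to 1116. Cholesterol synthesis genes were higher for 16 of 17 (1.03, 14 over the list alone, adjusted p = 0.746 with an estimated correlation). Unfolded protein response genes (15 of 16 lower, −0.54, 4) and hypoxia genes (20 of 23, −0.38, 5) were lower, each at adjusted p = 0.746 with an estimated correlation. Type I interferon targets were lower (−0.26, 0 over the list alone, adjusted p = 0.777 with an estimated correlation), a call lost without SK1 or DK1 (0.184 and 0.313). Genes of type 3 immunity were higher for 5 of 5 (2.32, adjusted p = 0.746 with an estimated correlation). Without SK2 or DK2 too few members of that list were tested. It was led by Tmem176b (log2 3.32) and Tmem176a (3.54), membrane channel genes that myeloid cells also express. Krt18 stood at 2.63 CPM ± 0.399 against 11.5 ± 5.30 (SD, n = 2 each). Macrophages held 58 genes called higher and 35 lower. These were 140 and 172 without SK2, 145 and 108 without DK1 and 96 and 46 without DK2. Cluster 12 (Arg1, Mmp12, Nos2) held 85.2% of the type in the single-knockout group and 46.7% in the other, with clusters 29 (Ccl8, Pf4, C1q) at 12.2% and 29.5% and 33 (C1q, Mertk) at 2.6% and 23.8%.

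Neutrophils, the largest tumour population, differed in antigen presentation and mitochondrial transcripts, with 92 genes called higher and 68 lower. The stefins Stfa1 (ENSMUSG00000071562, chromosome 16, 36276951 to 36285373) and Csta2, inhibitors of cysteine proteases, were at 120.0 CPM ± 7.14 and 127 ± 62.1 against 0.975 ± 0.468 and 0.258 ± 0.364 (SD, n = 2 each, log2 6.97, SE 0.35, and 9.34, SE 0.92, edgeR adjusted p = 0.00134 and 0.0186). They belong to a cluster of near-identical copies and are uncertain as single genes. Creg1, a secreted lysosomal glycoprotein, fell from 463 CPM ± 205 to 57.3 ± 9.15 (SD, n = 2 each, −2.96, SE 0.40; 0.0351), and H2-Q6 from 242 ± 14.4 to 27.5 ± 11.6 (−3.07, SE 0.32; 0.0231). MHC class I genes were lower for 18 of 18 (median −1.18, camera adjusted p = 2.5e-06, adjusted p = 0.755 with an estimated correlation, 11 over the list alone) and still called without the H2 region (0.00437). The 13 mitochondrially encoded genes were all higher (1.78, adjusted p = 0.746 with an estimated correlation), 10 passing over all genes. Siglecf, a lectin of eosinophils and of a subset of tumour neutrophils, rose by 2.91 (adjusted p = 0.0578 without SK1).

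Keratins and haemoglobin, which neutrophils do not make, differed too. The keratins Krt8 (1.81 CPM ± 0.374 against 17.2 ± 8.28, SD, n = 2 each), Krt18 (log2 3.64) and Krt19 (3.38) were called higher in tumour neutrophils, though not without SK1, and matrix genes, of untested source, were higher for 21 of 22 (median 2.27, adjusted p = 0.755 with an estimated correlation). Haemoglobin was lower for 5 of 5 (median −8.82, or −8.67 with genes of few counts at their bound, adjusted p = 0.746 with an estimated correlation), with Hba-a1 at 4103 against 3 UMIs, a ratio of 1697 with an interval of 580 to 8234. Cell cycle genes had a median of 2.66 (20 over the list alone, 0 over all genes, adjusted p = 0.755 with an estimated correlation) and cholesterol genes of 1.05 (8, 0.746 likewise). Precursor cluster 38 (Camp, Prtn3, Elane, Mpo), with 11, 2, 5 and 90 neutrophils in SK1, SK2, DK1 and DK2, held 5.45%, 5.49%, 9.56% and 56.9% of the cell cycle UMIs of the type. Interferon-γ targets (−1.13, 2 lower and 1 higher over the list alone, adjusted p = 0.785 with an estimated correlation) and type I targets (−0.68, 0, 0.814 likewise) were lower, and were lost without DK1, the latter also without SK1. Type 3 genes (1.23) and stress genes (0.42) were higher, each at adjusted p = 0.746 with an estimated correlation. Type 3 genes were lost without SK1 or DK1 and stress genes without SK2 or DK1. S100a8 (log2 1.01, SE 0.43), S100a9 (1.14, SE 0.43), Lcn2 (1.10, SE 0.35), Il1b (0.76, SE 0.28) and Cd274 (−0.97, SE 0.30) did not pass (edgeR adjusted p = 0.189, 0.154, 0.114, 0.151 and 0.107). Without SK1 28 and 9 neutrophil genes were called, without SK2 106 and 153, without DK1 500 and 200 and without DK2 241 and 157. Clusters 0 (24%, 13%), 1 (2.8%, 20%) and 5 (19%, 8.3%) led SK1 and SK2 pooled. Clusters 4 (2.8%, 22%), 8 (9.6%, 18%) and 7 (28%, 7.8%) led DK1 and DK2.

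Monocytes held 0 calls in edgeR, with 296 genes higher and 281 lower at an unadjusted p under 0.05 and 26 and 14 in DESeq2. As lists, cholesterol synthesis was higher in monocytes for 16 of 17 (median 0.81, camera adjusted p = 5.6e-10, 7 over the list alone) and the unfolded protein response lower for 13 of 15 (−0.71, 5.6e-10, 12), each at adjusted p = 0.746 with an estimated correlation. Hspa5 (log2 −1.03, SE 0.20), Creld2 (−1.30, SE 0.25) and Herpud1 (−1.21, SE 0.23), chaperone and quality control genes of the endoplasmic reticulum, did not pass (edgeR adjusted p = 0.474 each). MHC class II genes were lower (−0.83, 7 lower and 1 higher over the list alone, adjusted p = 0.755 with an estimated correlation). Genes of the regulatory T cell programme were higher for 8 of 8 (2.03, 6), among them Foxp3 and Ctla4, which are T cell transcripts. Antimicrobial (1.27, 3), type 2 immunity (0.57, 0) and matrix genes (1.08, 2) were also higher, and all 4 of these lists stood at adjusted p = 0.746 with an estimated correlation. Hypoxia (0.45, 0) and mitochondrially encoded genes (0.28, 0) were higher at adjusted p = 0.755 and 0.785 with an estimated correlation, the first lost without SK1 (0.618) and the second without SK2 or DK1 (0.448 and 0.293). The type 2 call was lost without SK1 or DK1 (0.121 and 0.111).

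CD4 T cells, regulatory T cells and NK cells of the tumours shared the higher cell cycle list (medians 0.81, 0.75 and 0.39, adjusted p = 0.746, 0.755 and 0.746 with an estimated correlation, 2, 0 and 3 over the list alone). The call in regulatory T cells was lost without SK1 (0.129). Cholesterol genes were higher in CD4 (1.26, 3) and regulatory T cells (1.20, 4), each at adjusted p = 0.746 with an estimated correlation. In CD4 T cells interferon-γ targets (17 of 18 lower, −0.63, 0), type I targets (13 of 13, −0.43, 0) and MHC class I genes (−0.24, 4) were lower, and matrix genes higher (0.48, 1), at adjusted p = 0.746, 0.755, 0.746 and 0.746 with an estimated correlation. Without the H2 region the MHC class I call was lost (0.199). Without DK1 the type I, MHC class I and matrix calls were lost (0.105, 0.0578 and 0.407), the last also without SK1 (0.198). Interferon-γ targets were lower in regulatory T cells (−0.42, 1, adjusted p = 0.755 with an estimated correlation), but not without SK1 (0.749), and inhibitory receptor genes higher in NK cells (0.48, 4 higher and 2 lower over the list alone, adjusted p = 0.755 with an estimated correlation), a call lost without SK2, DK1 or DK2 (0.817, 0.264 and 0.0836). In NK cells Klra5, a receptor of the Ly49 family whose members share reads, was at 235 CPM ± 58.5 against 13.4 ± 2.77 (SD, n = 2 each, log2 4.20, SE 0.47, edgeR adjusted p = 0.0107). Txnip, an inhibitor of glucose uptake, fell by 2.01 (SE 0.25; 0.0182) in NK cells and was also called lower in CD8 T cells (log2 −1.97) and macrophages (−2.31). Both NK calls ended without SK1 (0.328 each) or SK2 (0.0680 and 0.0790). Foxp3 in regulatory T cells (−0.11, SE 0.19), Il17a in CD4 T cells (−0.77, SE 0.60) and Igha in NK cells (3.26, SE 0.88) did not pass (0.944, 0.845 and 0.350), though Igha did without DK2 (2.96e-11).

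**Figure D3:**
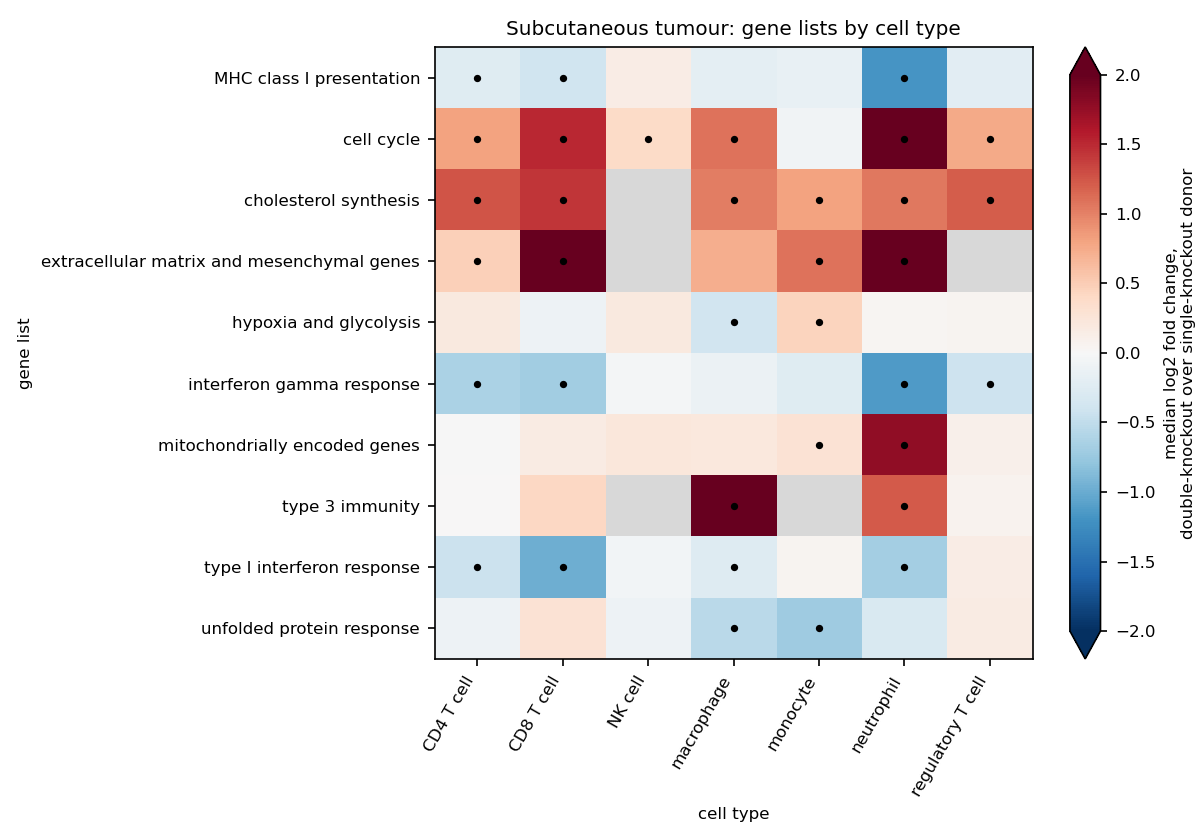
Heat map of the median log2 fold change of each gene list (vertical axis) in each tumour cell type (horizontal axis), double-knockout over single-knockout donor group, on a colour scale from −2 to 2; a black dot marks a camera call, grey means not tested, and the lists called in at least 2 types are drawn. Cell cycle is called higher in 6 of 7 types and cholesterol synthesis in 6 of 6.

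A small set of genes differed in several tumour types at once. The predicted gene Gm10260 (ENSMUSG00000069117, chromosome 13, 97760072 to 97760632), singled out after its values were seen, was called higher in 6 of 7 types. In CD4 and regulatory T cells 2492 and 2330 UMIs stood against 0, at least 387-fold and at least 222-fold higher at the floor of 3 counts over the group. In macrophages it was 4809 against 1 UMIs, a ratio of 3999 with an interval of 717 to 157977, and in CD8 T cells 1487 against 0.642 CPM. H2-Q2 (ENSMUSG00000091705, chromosome 17, 35342242 to 35346762), a class I gene, was higher in CD8 T cells (28.8 CPM ± 0.377 against 0.637 ± 0.173, log2 5.48, SE 0.32, edgeR adjusted p = 0.0151) and macrophages (32.8 ± 14.0 against 0.364 ± 0.515, 5.64, SE 0.60; 0.00943, SD, n = 2 each). H2-Q1, BC023719 and Gm8909 of the same chromosome were, like H2-Q2, called in CD8 T cells, macrophages and neutrophils, H2-Q1 in macrophages not without DK2 (0.0616). AI506816, an unnamed transcript on chromosome 5, rose in CD8 T cells to 104 CPM ± 29.5 from 7.67 ± 1.90 (log2 3.81, SE 0.29; 0.0241, SD, n = 2 each). In lamina propria macrophages Gm10260 stood at 0.166 and 10.2 CPM in the single-knockout group and at 1.02 and 386 in the other, so it also separated the pair of libraries within that group.

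Over all 7 tumour types 291 gene calls were higher and 151 lower, 65.8% higher, among 60540 tests with 8723 at an unadjusted p under 0.05. In all 442 the donor groups did not overlap, as calling favours, and 75 calls held in all 4 fits leaving out a library. DESeq2 called 1078 and 766. Leaving out SK1 or SK2, the libraries with sex labels that the transcripts went against, gave 147 and 68 or 497 and 523, and leaving out DK1 or DK2 739 and 389 or 491 and 265. Of 150 list and type pairs 46 were called, 27 higher and 19 lower, with 28 in all 4 of those fits and 72 without SK2. Camera with an estimated correlation and fry called 0, with 6 and 28 pairs at an unadjusted p under 0.05. NF-κB targets, angiogenesis, immunoglobulin, barrier, sex-specific and suppressive macrophage genes were not called in any tumour type, and aryl hydrocarbon receptor targets had too few members to test.

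Tumour cell shares did not pass for any of 19 types in edgeR (0 called, 5 at an unadjusted p under 0.05, lowest adjusted p = 0.0690). Carcinoma cells were 0.565% ± 0.287 of kept cells against 8.18% ± 0.0998 (SD, n = 2 each, log2 3.84, SE 0.84, adjusted p = 0.0690, exact p = 0.333) and fibroblasts 0.200% ± 0.132 against 2.78% ± 1.44 (3.76, SE 0.95; 0.0696, exact p = 0.333). Endothelial cells (0.0442% ± 0.0279 against 0.365% ± 0.00998, adjusted p = 0.0854), mature dendritic cells (0.155% ± 0.0390 against 0.730% ± 0.0183, 0.122) and plasmacytoid dendritic cells (0.126% ± 0.0925 against 0.641% ± 0.0891, 0.138, SD, n = 2 each, exact p = 0.333 each) had the other estimates of low p. Leaving out SK1 gave 3 calls, for carcinoma, endothelial and plasmacytoid dendritic cells, and leaving out SK2 also gave 3, carcinoma cells among them. Naive T and B cells made up 8.03% and 4.92% of SK1, the library labelled male, and under 1% of each other tumour library. The latter lay in cluster 27, which had Jchain, Mzb1 and immunoglobulin genes among its leading genes beside Cd79a, Cd79b and Bank1, so this class also carries plasma cell transcripts. Neutrophils were 58.6% and 78.2% against 59.6% and 56.4%, and CD8 T cells 10.0% ± 4.63 against 6.73% ± 0.0991 (SD, n = 2 each). Dissociation and the live-cell sort can set these shares.

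**Figure D4:**
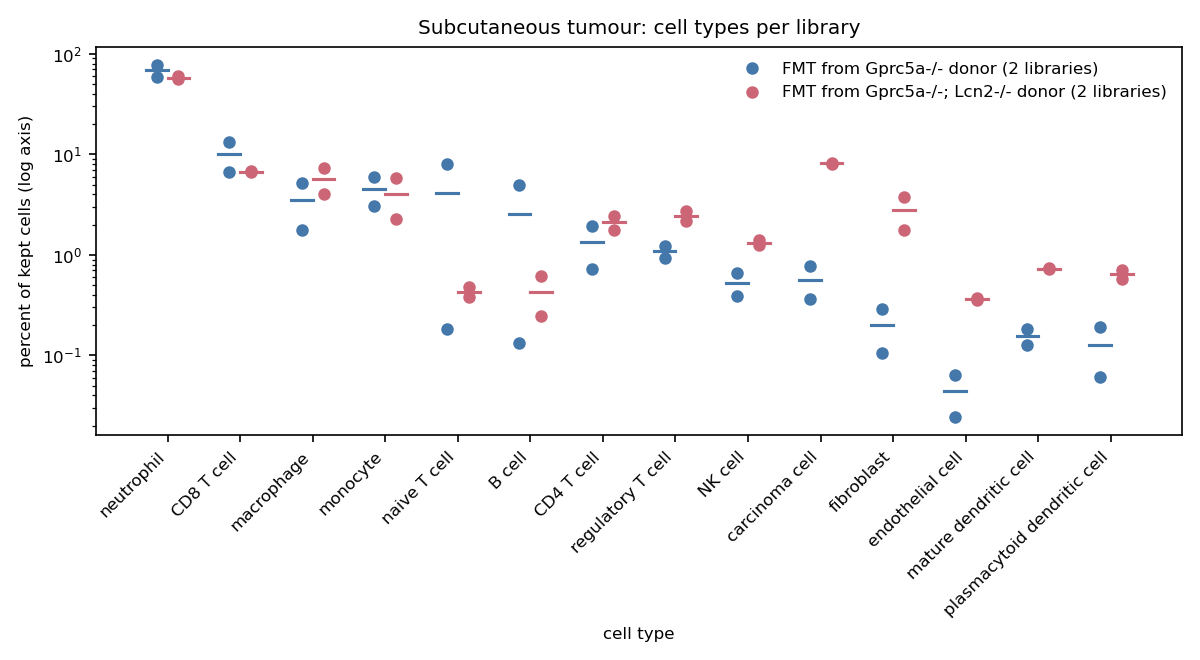
Percent of kept cells (vertical axis, log scale) for 14 tumour cell types (horizontal axis), with a point per library and a bar at the mean of each donor group of 2 libraries. Carcinoma cells lie at 0.362% and 0.768% in the single-knockout and at 8.26% and 8.11% in the double-knockout donor group, and no type passed the test.

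Whether the donor effect differed between the tissues was tested in the 3 types with enough cells in all 8 libraries: CD8 T cells, macrophages and regulatory T cells. The effect differed for 18 genes in edgeR, 16 in macrophages and 2 in CD8 T cells, among 29672 tests with 2988 at an unadjusted p under 0.05. In CD8 T cells Ccl5 had a tumour minus lamina propria difference of −2.85 (SE 0.33, adjusted p = 0.0413), being lower in tumours and at 10065 CPM ± 3267 against 10156 ± 482 (SD, n = 2 each) in lamina propria. In macrophages Selenop (3.099, SE 0.31) and Tmem176b (3.64, SE 0.39) rose in tumours more than in lamina propria and Il6 (−3.15, SE 0.37) went lower (each 0.0191). Regulatory T cells had 0 genes, with 423 of 7268 at an unadjusted p under 0.05. DESeq2 gave 176 genes and fits without shared barcodes 10. With the replicate block 0 of the 18 remained (adjusted p = 0.0513 to 0.170), and 1 other gene was called. The crossed block kept 11 of the 18 and naming cells by the best marker list 0. Without lamina propria DK1 or DK2 0 were called in edgeR, and without tumour DK2 6. Of the 18, 4 held without tumour SK2 and 4 without tumour DK2. The shifts of gene lists were not tested for a difference between the tissues.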

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

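No test in this part was chosen only after its result was seen, except the fits without shared barcodes. The effect of the microbiota donor differed between tumours and lamina propria for 18 genes, by an interaction test in edgeR over all 8 libraries. Values are the tumour log2 fold change minus that in lamina propria. In CD8 T cells the chemokine Ccl5 differed by −2.85 and Camk2n1, an inhibitor of a calmodulin kinase, by −2.74 (adjusted p = 0.0413 each). The tumour donor groups did not overlap for either gene, nor the lamina propria groups for Camk2n1, which went the other way there (0.77, SE 0.23) without passing.

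In macrophages 9 genes were more positive in tumours. Tmem176a (3.89) and Tmem176b (3.64) code for membrane channels, Hpgds (3.72) for a prostaglandin D synthase, Selenop (3.099) for a selenium carrier and Fgd2 (2.70) for an exchange factor of small GTPases. The deacetylase Hdac9 (2.11), the tetraspanin Cd63 (1.90) and the sorting nexin Snx24 (1.85) were smaller differences. Ccl8 had a fitted difference of 9.25, which rests on 2 UMIs in the tumour single-knockout group and is no bound. The 7 genes more negative in tumours were the cytokine Il6 (−3.15), the integrin Itga1 (−2.91), Glipr2 (−2.72), Ecm1 (−2.70), the chemokine Ccl9 (−2.32), Rgcc (−2.32) and Crip1 (−1.68). Adjusted p lay between 0.0191 and 0.0456 in edgeR. Itga1 (tumour −0.85, adjusted p = 0.211; lamina propria 2.05, 0.171) and Crip1 (−0.18, 0.806; 1.49, 0.126) passed in neither tissue alone. Without lamina propria DK1 or DK2 0 genes differed, and without tumour DK2 6 did. Of the 18 calls 4 held without tumour SK2, when 18 were made, and 4 without tumour DK2. Without shared barcodes the count was 10. The replicate block ended all 18 calls, which stood at 0.0513 to 0.170, and left 1 other gene. Naming cells by the best marker list also ended all 18.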

How the results depend on the processing

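Of the tests in this part, those without shared barcodes, without the H2 region and Gm10260, and with crossed replicate numbers were chosen only after the result was seen. Other settings moved counts of called genes far more than the direction of named genes. Of 38 named lamina propria genes tested under alternatives, 544 of 684 values kept direction and side of the threshold, 107 newly passed, 21 no longer passed and 12 turned direction. For 36 named tumour genes these were 530 of 596, with 26, 31 and 9. For the 18 interaction genes 244 of 413 values held and 169 no longer passed, and for 6 cell shares 51 of 55 held and 4 newly passed. DESeq2 gave no adjusted p for Cxcl9 in type 1 dendritic cells, nor, without shared barcodes, for the Itga1 interaction, and these are not counted.

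Counts of calls in edgeR moved by over 1.5 times as follows, and the cause was not tested unless stated. In lamina propria, 4 genes higher and 11 lower became 198 and 101 in DESeq2, 1283 and 891 with no low-count filter, and 7 and 18 with summed counts thinned to the smallest library. Requiring 50 cells per library gave 0 and 2, since fewer types were tested. Without shared barcodes 14 and 6 were called, or 215 and 90 in DESeq2, and without the H2 region and Gm10260 8 were higher. Leaving out a library gave 257 to 1008 higher and 168 to 704 lower, the most without SK2. In tumours 291 higher and 151 lower became 1078 and 766 in DESeq2 and 2767 and 1773 with no low-count filter. Leaving out a library gave 147 to 739 and 68 to 523. The 18 interaction genes became 176 in DESeq2, 898 with no low-count filter, 6 without doublet removal, 2 with cells named by the best marker list, 10 without shared barcodes and 161 with DESeq2 as well. Leaving out a library gave 0 to 24. The 88 list and type pairs of the lamina propria became 156 and the 46 of the tumours 128 with the best marker list, and both became 0 with an estimated correlation, also without shared barcodes, and with fry. Leaving out a library gave 90 to 149 and 46 to 72 pairs. Cell shares held 0 calls in lamina propria under every alternative and 0 to 3 in tumours, where 3 were called without SK1 and 3 without SK2. DESeq2 scaling, the free RNA filter, at least 1000 UMIs and at most 10% mitochondrial counts moved no count by over 1.5 times.

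The replicate number was also the labelled sex. Libraries of the same number deviated together with a median correlation of 0.00419 over 19 lamina propria types and −0.10 over 7 tumour types, the highest 0.260 in lamina propria epithelial cells, and the labels tie the number to sex but to no shared animal, litter or day. With the replicate block, calls were 120 higher and 114 lower in lamina propria, 828 and 465 in tumours, and 1 interaction gene. With it 86 of the 88 lamina propria list calls and all 46 of the tumours remained. A crossed replicate block, which pairs libraries of like Ddx3y in tumours but not in lamina propria, gave 59 and 69, 687 and 486, and 18.

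Direction turned for these named genes, and only Il17a in lamina propria without SK1 passed after turning. Without doublet removal Igha in type 1 dendritic cells had a log2 estimate of 1.96 and Il22ra2 in type 2 dendritic cells of −0.045. Igha in plasma cells was at −0.017 without shared barcodes and at −0.019 without them in DESeq2, and Cd274 in B cells of the colonic lamina propria at −0.016 with thinned counts. Ifng in lamina propria CD8 T cells was at −0.31 with the best marker list. In tumour CD8 T cells Ifng was at −0.019 with the replicate block and −0.021 with crossed numbers, and Cd8a at 0.013 with the best marker list. Estimates that turned when a library was left out spanned these ranges over the 4 fits, in which the lone library is assumed to vary like the other pair. In lamina propria they were −0.031 to 0.11 for Igha in plasma cells, −0.033 to 0.47 for Cd274 in B cells, −1.40 to 2.03 for S100a9 in innate lymphoid cells, −3.31 to 1.74 for Il17a in the Il23r and Cxcr6 cluster (adjusted p = 0.0114 at 1.74, without SK1), and −0.32 to 1.32 for Ifng and −1.11 to 0.087 for Cd8a in CD8 T cells. In tumours they were −0.62 to 0.52 for Ifng and −0.17 to 0.10 for Cd8a in CD8 T cells, −1.51 to 1.00 for Il17a in CD4 T cells and −0.25 to 0.045 for Foxp3 in regulatory T cells. The cause was not tested in any of these. With 2 libraries per group a 2-fold change was recovered in simulation for between 6.12% and 36.5% of genes, so a missing call says little.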

Other observations

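Of the tests below, the comparison of barcode sharing with chance and the 3 tests on the H2 genes and Gm10260 were chosen only after the result was seen, and so were the fits without shared barcodes. Further genes called in tumour neutrophils and macrophages were chosen after their values were seen. Clusterin, Clu, an extracellular chaperone, was higher in both main myeloid types: 34.1 CPM ± 3.80 against 1.30 ± 0.0125 in neutrophils (log2 4.81, SE 0.29; edgeR adjusted p = 0.00192) and 15.6 ± 4.56 against 0.546 ± 0.773 in macrophages (3.93, SE 0.60; 0.0298; SD, n = 2 each). Clu was also a leading gene of carcinoma cluster 23. Carcinoma cells, 8.18% against 0.565% of kept cells, had 4464 CPM ± 807 of Clu and 2949 ± 494 of Krt18 in the double-knockout group (SD, n = 2). In neutrophils Krt18 stood at 26.6 CPM ± 13.1 against 2.22 ± 1.32 (SD, n = 2 each), so carcinoma RNA could account for the Clu rise. In neutrophils annexin A1, Anxa1, which ends neutrophil recruitment, stood at 606 CPM ± 17.9 against 126 ± 30.7 (SD, n = 2 each; log2 2.33, SE 0.29; 0.0284). In macrophages the collagenase Mmp13 stood at 165 CPM ± 11.3 against 14.2 ± 1.81 (SD, n = 2 each; log2 3.40, SE 0.23; 0.00162), but it was also a leading gene of fibroblast cluster 35, with 2150 and 152 CPM in double-knockout group fibroblasts. For each of these genes the donor groups did not overlap, and each call held in all 4 fits leaving out a library.

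The barcodes that lamina propria SK2 shared with its tissue partners were weighed on 3 explanations. Chance reuse of the common barcode list is argued against, since the lowest sharing rate of this library was 7.90 times the highest rate of pairs without it. Molecules of the other lamina propria libraries read into this one remain a candidate explanation: 94.2% of 9107 pairs had the same cell type against 25.5% by chance, a ratio of 3.69, and Ddx3y in this library, labelled female, went from 7.24 to 0.111 CPM without them. Whether these cells dilute the interferon contrast stays open: without them the median over 467 list gene and type pairs moved from −0.45 to −0.48, by 0.0353. The bound of 0.1 set for this test was out of reach, as 21.4% of the library's UMIs at the level of the other donor group would move the median by 0.0313. No biological explanation was tested for this pattern.

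Gm10260, H2-Q1, H2-Q2, BC023719 and Gm8909 were called higher in at least 3 tumour types each. Carcinoma RNA is argued against, since keratins accounted for 1.11% of the Gm10260 level in tumour macrophages, and so is the microbiota donor acting in both tissues, since 0 of the 5 genes had both lamina propria libraries of the double-knockout group beyond both of the other. A candidate explanation is a strain variant carried by some recipients: macrophages of the 2 lamina propria double-knockout libraries differed from each other by a median log2 of 4.42, 0.986 times the difference of 4.48 between tumour groups. Carcinoma cells carried Gm10260 in all 4 tumour libraries, at 700 and 1837 CPM in the single-knockout group, where macrophages had 0 and 0.182. In tumours both double-knockout libraries carried the higher level and neither single-knockout library did. If recipient background differed in this way, it cannot be told apart from the donor there, for these genes or for any other tumour difference.

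Higher cell cycle genes in tumour CD8 T cells were weighed on the 16 called members. Carcinoma RNA is argued against, as keratins accounted for 0.0688% of the rise. With summed counts thinned, the median log2 change was 1.86 against 1.93 (0.964 times), but thinning keeps expected gene shares, so depth stays open. UMIs per cell and cell numbers were not matched. More cells sat outside the 3 clusters of low Mki67, 22 of 624 and 36 of 553 against 46 of 242 and 184 of 512. How much of the rise this accounts for stays open: within the 3 of 8 clusters of low Mki67 the median difference was 0.93 against 1.85 in the whole class, a ratio of 0.503 that lies between the bounds set for either. The microbiota donor also stays open, untested apart from the recipient background.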
